A study of Rattus norvegicus with 60 samples.

How the data were processed

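RNA was measured in kidney cortex and outer medulla of wild-type Dahl salt-sensitive rats (SS) and of a NOX4 knockout line derived from them (NOX4). Rats were sampled under control conditions (LS) or after 7 days (HS7) or 21 days (HS21) on a diet with 4.0% NaCl. The 12 groups of strain, diet and tissue held 5 libraries each, 60 in all. Per the labels' protocols, RNA was extracted from snap-frozen tissue with Trizol, cleaned on a column and made into poly(A)-enriched libraries. The labels give no sex, age, strandedness, library date or salt content of the control diet.

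Per the submitters' processing notes, the authors aligned reads with HISAT2 2.0.5, used StringTie 1.3.3b and counted reads per gene with featureCounts 1.5.0-p3. Per the file headers, the deposited values are a raw read count per gene and library, an FPKM per gene and library, and for 18 comparisons a log2 fold change, a p-value and an adjusted p-value. The tool behind the deposited tests is not stated. Within a library the deposited FPKM was proportional to the count over gene length, at 0.788 to 1.18 times the FPKM computed from the library's own total. Gene names, lengths and positions were used as deposited; the genome build is not stated, and the contig names are those of Rnor_6.0. List symbols were matched through the deposited names and, for older names, an annotation of the GRCr8 assembly, from which no coordinate was taken.

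The deposited counts of 32545 genes were analysed in R 4.3.3 with edgeR 4.0.16. Genes passed filterByExpr by group, which left 15179 in cortex, 15799 in outer medulla and 16326 with both tissues together. Counts were scaled by TMM. A quasi-likelihood F test compared groups in a model with 1 coefficient per group, fitted over the 30 libraries of a tissue, or over all 60 for comparisons between tissues. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. The standard error of a log2 fold change is its size divided by the square root of F. Levels are given in CPM (counts scaled to the library total multiplied by its TMM factor) as mean ± SD. Sequencing reads carry no molecular identifiers, so counts per library also hold amplified copies.

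Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, 2-sided, with a preset correlation between genes of 0.01 and adjustment over all lists of a comparison. Each was repeated with the correlation estimated from the data. The 49 lists held 1067 entries, of which 1026 matched a gene, and lists with fewer than 5 tested members were not tested. Beside each test stands the number of members called over all genes and the number called when adjusted over the list alone. Nox4 was also compared between strains by an exact permutation test over all 252 splits of 5 against 5 libraries, 2-sided.

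The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule gave Nox4; the 8 highest and 8 lowest log2 fold changes among called genes for strain averaged over diets; 6 and 6 for each diet against LS; 3 and 3 for strain at each diet; the 4 smallest p-values for interactions, tissue differences and HS21 against HS7; up to 4 called members per list; and segment markers for the tissues. Such genes needed a mean CPM of at least 1 in a compared group and a given symbol. Of these, the text names mainly those still called when any 1 library was left out, a restriction chosen after the values were seen. The numbers of libraries on the stated side of a mean follow in part from this choice and are not separate support. Genes given for salt in NOX4 were also chosen after their values were seen.

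On simulated counts made from the cortex libraries for NOX4 against SS at LS (15083 genes tested), the test called 46.3% of genes changed 1.5-fold, 56.7% of those changed 2-fold and 89.4% of those changed 4-fold, with 3 calls among unchanged genes. For outer medulla (15684 genes tested) the shares were 13.4%, 64.2% and 93.9%, also with 3 such calls. The simulated libraries were drawn independently with 1 dispersion per gene, without differences in library quality or tissue composition. Neither the shares nor the few calls among unchanged genes need hold for the real libraries.

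Library totals ran from 11.5 to 29.6 M counts. Thinned to 10 M counts, 49 libraries held 16929 to 18402 genes. The other 11, all SS libraries at LS or HS7 (5 in cortex, 6 in outer medulla), held 14078 to 16119, and in each at least 10 of the genes with a tissue median of 2 to 5 CPM had no count. They are called low-complexity libraries. The library names run in group order, with SS at LS and HS7 first, then SS at HS21 and then NOX4. Every SS library thus precedes every NOX4 library.

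Alternatives fixed at the outset were DESeq2's size factors within edgeR, DESeq2 1.42.0 with its Wald test, no filter on low counts, a filter of 1 CPM in 5 libraries, a fit of the compared groups alone, the replicate number as a block, a podocyte score as covariate in outer medulla, leaving out NOX4 HS7 cortex replicates 3 and 4 (whose library names break the order), an estimated correlation for lists, and leaving out each library. Chosen after seeing the data were leaving out low-complexity libraries, limma voom with quality weights, a proximal tubule segment 3 score (mean log2 CPM of the list) as covariate, and leaving out NOX4 HS7 outer medulla replicates 3 and 4. Figures were drawn with matplotlib.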

Results

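Gene expression was measured by poly(A) RNA sequencing in kidney cortex and outer medulla of Dahl salt-sensitive rats (SS) and of rats of a derived NOX4 knockout line (NOX4), at LS, HS7 and HS21. Each of the 12 groups had 5 libraries. Mean totals per group ran from 14.4 M counts (SS LS outer medulla, SD 2.59) to 23.6 M (SS HS21 outer medulla, SD 3.60). The study asks how loss of NADPH oxidase 4, an enzyme that makes hydrogen peroxide in renal tubules, bears on metabolic stress in the kidney of a rat that becomes hypertensive on salt.

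The targeted gene was lower in NOX4 cortex at each diet. Nox4 (ENSRNOG00000013925, chromosome 1, 150797084 to 150976194, plus strand) had 317 ± 74.3 CPM (SD, n = 5) in SS cortex at LS and 66.5 ± 9.14 CPM in NOX4 cortex. At HS7 the levels were 426 ± 102 and 65.3 ± 2.51 CPM, and at HS21 they were 316 ± 44.2 and 65.7 ± 7.73 CPM. NOX4 cortex thus held 15.3% to 21.0% of the SS level, with no overlap between libraries of the strains. The exact permutation p was 0.00794 at each diet in cortex, the smallest that 252 splits allow. In outer medulla SS had 9.75 ± 2.54, 35.7 ± 43.9 and 14.3 ± 6.47 CPM at LS, HS7 and HS21, against 5.04 ± 3.03, 5.85 ± 5.23 and 5.2 ± 2.08 CPM in NOX4. There the exact permutation p was 0.0397, 0.0794 and 0.00794, while edgeR gave log2 fold changes of -0.94 ± 0.60 (adjusted p = 0.293, 4 of 5 NOX4 libraries under the SS mean), -2.62 ± 0.62 (0.0104, 5 of 5) and -1.47 ± 0.60 (0.208, 5 of 5). Averaged over diets it was lower there too (-1.68 ± 0.35, adjusted p = 0.000836). SS HS7 replicate 3 had 111 CPM and the highest score of proximal tubule segments 1 and 2 among outer medulla libraries (8.37); without it the SS mean at HS7 was 17 ± 14.7 CPM. A gene-level count does not show which exons the remaining reads came from. Leaving out any of 8 of the 10 outer medulla libraries at LS took that exact p over 0.05 (to between 0.0556 and 0.0794), and at HS7 leaving out SS replicate 1 or 2 took it to 0.0238 or 0.0317.

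**Figure D1:**
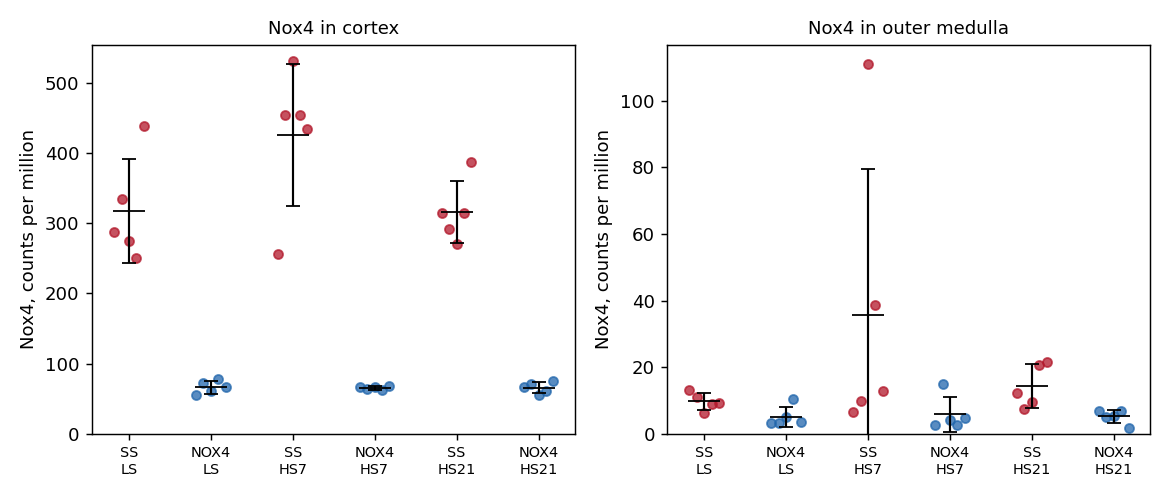
Nox4 in CPM in each library of cortex (left) and outer medulla (right); points are libraries, bars the mean and SD of 5 libraries, red SS and blue NOX4. In cortex every NOX4 library lies below every SS library, at 54.7 to 77.7 CPM; the vertical scales differ between tissues.

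After 21 days of high salt, NOX4 cortex had lower expression of matrix, injury and complement genes than SS cortex and higher expression of distal nephron and glomerular genes. Of 42 tested extracellular matrix and fibrosis genes, 17 fell and none rose, and 35 fell when adjusted over the list alone, with a median log2 fold change of -0.66. Among them were Fn1, which encodes fibronectin (-1.2 ± 0.16 SE; 104 ± 15.3 CPM in NOX4 and 238 ± 41.2 CPM in SS), the proteoglycan gene Dcn (-0.91 ± 0.16), Col6a1 (-0.80 ± 0.14) and the cross-linking enzyme gene Loxl1 (-0.66 ± 0.12). Of 32 tubular injury genes 6 fell, 18 when adjusted over the list alone, with a median of -0.41. Sox9, a transcription factor of tubular repair, had -1.49 ± 0.30 and ceruloplasmin (Cp) -1.03 ± 0.18. Of 29 complement and coagulation genes 9 fell and 1 rose (15 and 2 adjusted over the list alone; median -0.62), C1r among them (-0.65 ± 0.12). Of 36 cytokine, chemokine and adhesion genes 2 fell, 4 adjusted over the list alone, with a median of -0.31. These lists fell together at adjusted p of 5.32e-43, 1.56e-15, 8.65e-14 and 3.81e-07 by camera, and with an estimated correlation at adjusted p = 0.0138, 0.0204, 0.0140 and 0.0436.

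The lists that rose together in NOX4 cortex at HS21 covered the distal nephron, podocytes and nuclear genes of the respiratory chain. Whether the pieces of the strains differed in their share of distal nephron cells and podocytes was not tested. Of 17 markers of intercalated cells, which move acid in the collecting duct, 4 rose and 13 rose when adjusted over the list alone (median 0.61), with Atp6v0d2 at 0.63 ± 0.12. Of 15 principal cell markers 2 rose (9 adjusted over the list alone; median 0.53), and of 11 distal convoluted tubule markers 1 rose (7; median 0.34). Of 37 sodium and potassium transport genes 2 rose (15 adjusted over the list alone; median 0.25), with the potassium channel gene Kcnj1 at 0.57 ± 0.10. Of 13 podocyte genes 4 rose (10 adjusted over the list alone; median 0.39), with Sema3g at 0.68 ± 0.12. Of 32 nuclear genes of respiratory chain complex I, 2 rose (16 adjusted over the list alone; median 0.22). With an estimated correlation these 6 lists had adjusted p = 0.0191, 0.0140, 0.0140, 0.0140, 0.0191 and 0.0204. Complexes II to V had 0 of 38 members called (16 rose adjusted over the list alone; median 0.21), and the call on that list ended with adjusted p = 0.051 with an estimated correlation.

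In all, edgeR called 152 of 15179 genes between the strains in cortex at HS21, 51 of them higher in NOX4 and the others lower. All SS libraries precede all NOX4 libraries in library order, so strain and order coincide at HS21. The named genes had adjusted p between 0.00036 (Fn1) and 0.0112 (Sox9) and lay on the stated side of the SS mean in 5 of 5 NOX4 libraries. The segment 3 score (mean log2 CPM of markers of proximal tubule segment 3) was 5.37 ± 0.40 in NOX4 and 6.11 ± 0.59 in SS (SD, n = 5), and with that score as covariate 60 genes were called. A fit without the low-complexity libraries called 583, DESeq2 339, a fit of the compared groups alone 1237 and limma voom with quality weights 2161. The deposited adjusted p-values gave 1937, all 152 among them. Leaving out any of 8 of the 10 libraries moved it over 1.5-fold, from 29 without SS HS21 replicate 3 to 290 without SS HS21 replicate 5.

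In outer medulla at HS21 the same comparison showed lower matrix and smooth muscle genes in NOX4 and higher genes of mitochondrial energy metabolism. Of 42 matrix genes 29 fell and none rose, and 37 fell when adjusted over the list alone, with a median of -1.13. The elastin gene Eln had -2.12 ± 0.32 (40.8 ± 22.4 CPM in NOX4 and 178 ± 96.7 CPM in SS, n = 5 each) and the tenascin gene Tnc -2.01 ± 0.35. Acta2, which encodes smooth muscle actin, had -1.56 ± 0.27. Of 16 smooth muscle and pericyte genes, Acta2 included, 4 fell (6 adjusted over the list alone; median -0.52), with Tagln at -1.42 ± 0.26 and Des at -0.89 ± 0.16. The endothelin receptor gene Ednra had -0.90 ± 0.18. Of 32 tubular injury genes 7 fell (16 adjusted over the list alone; median -0.58). With an estimated correlation the calls on these 3 lists ended, at adjusted p = 0.0919, 0.0919 and 0.147. Of 32 complex I genes 9 rose and all 32 rose when adjusted over the list alone (median 0.43). Of 38 genes of complexes II to V 3 rose and 35 adjusted over the list alone (median 0.42). Of 33 fatty acid oxidation genes 1 rose and 22 adjusted over the list alone (median 0.51), and of 19 tricarboxylic acid cycle genes 2 and 14 (median 0.41). These calls also ended, with adjusted p = 0.144, 0.144, 0.148 and 0.148 with an estimated correlation. How far the rise of fatty acid oxidation genes follows the share of proximal tubule in the pieces stays open. Fdft1, of cholesterol synthesis, rose by 0.70 ± 0.14.

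In all, 258 of 15799 genes were called, 48 higher and 210 lower, at adjusted p between 0.00233 (Eln) and 0.00993 (Ednra) for the genes named, each in 5 of 5 NOX4 libraries. The segment 3 score was 6.80 ± 0.44 in NOX4 and 5.54 ± 0.89 in SS (SD, n = 5), and with that score as covariate 12 genes were called. Strain and library order coincide here too. The replicate block gave 146 and no filter on low counts 171. DESeq2 called 640, a fit without the low-complexity libraries 2297, a fit of the compared groups alone 3703 and limma voom with quality weights 7461. The deposited values gave 5446, all 258 among them. Leaving out any of 9 of the 10 libraries moved the count over 1.5-fold, from 28 without NOX4 HS21 replicate 4 to 834 without SS HS21 replicate 5.

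**Figure D2:**
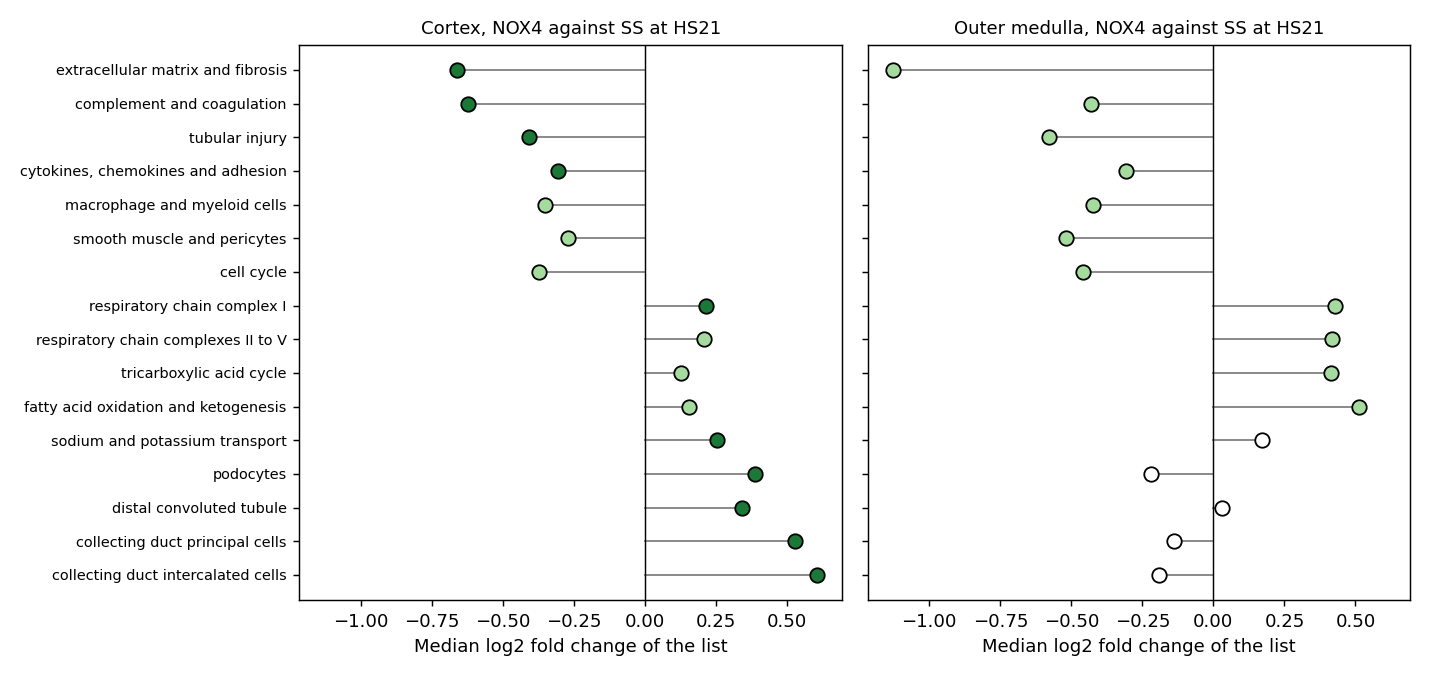
Median log2 fold change of 16 gene lists, NOX4 against SS at HS21, in cortex (left) and outer medulla (right). Dark points are lists called by camera with the preset and with the estimated correlation, pale points lists called with the preset alone, open points lists not called; matrix genes lie at -0.66 in cortex and -1.13 in outer medulla.

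Averaged over the 3 diets, the strains differed most broadly. In cortex, collecting duct, podocyte, transport, nuclear complex I and fatty acid oxidation lists were higher in NOX4 by the preset correlation. The mean mitochondrial read share was 14.4%, 14.8% and 11.9% in SS cortex at LS, HS7 and HS21. In NOX4 cortex it was 13.5%, 12.6% and 12.7%, so mitochondrially encoded transcripts were not a higher share at LS or HS7. Whether the pieces differed in their share of collecting duct cells and podocytes was not tested. Of 17 intercalated cell markers 15 rose and none fell (median 0.58), with the ammonia transporter genes Rhcg (0.67 ± 0.08) and Rhbg (0.74 ± 0.09) and the anion exchanger gene Slc26a4 (0.78 ± 0.13). Of 15 principal cell markers 10 rose (Aqp2 0.65 ± 0.11, Aqp3 0.57 ± 0.08), of 13 podocyte genes 10 (Nphs1 0.57 ± 0.09, Sema3g 0.73 ± 0.07), and of 37 sodium and potassium transport genes 21 rose and 2 fell (Slc12a3 0.71 ± 0.11). Complex I had 19 of 32 genes higher (Ndufa13 0.49 ± 0.07), and fatty acid oxidation 14 of 33 higher and 2 lower (Acaa1a, a peroxisomal thiolase gene, 0.75 ± 0.08). Adjusted over the list alone the higher genes of these 6 lists numbered 15, 10, 12, 24, 20 and 18. The calls on these lists ended with adjusted p = 0.268, 0.268, 0.268, 0.268, 0.368 and 0.481 with an estimated correlation. At each of the 3 diets strain coincides with library order, as every SS library precedes every NOX4 library. SS at LS and HS7 hold all 11 low-complexity libraries (5 in cortex, 6 in outer medulla).

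Lower in NOX4 cortex, averaged over diets, were 28 of 42 matrix genes against 1 higher (30 and 1 adjusted over the list alone; median -0.40), with Fn1 at -0.89 ± 0.09 and Dcn at -0.76 ± 0.09. Also lower were 18 of 32 tubular injury genes against 2 higher (18 and 3 adjusted over the list alone), with Spp1, which encodes osteopontin, at -1.32 ± 0.20, and 10 of 32 cell cycle genes (10 adjusted over the list alone; Mki67 -0.81 ± 0.25, and -0.60 without NOX4 HS7 replicates 3 and 4). With an estimated correlation the adjusted p = 0.268, 0.292 and 0.496, and the calls on these lists ended. The cell cycle score was 2.40 in NOX4 and 2.96 in SS (mean log2 CPM), but 0.60 and 0.62 in NOX4 HS7 replicates 3 and 4, and 2.67 in NOX4 without them. The matrix score was 5.27 in NOX4 and 5.72 in SS, but 4.57 and 4.74 in these 2 libraries, and 5.36 in NOX4 without them. The red blood cell score was 3.05 in NOX4 and 3.39 in SS, 0.83 and 1.06 in these libraries, and 3.37 in NOX4 without them. The angiotensinogen gene Agt (-1.64 ± 0.27) and the peptidase gene Mme (-1.33 ± 0.20) fell. Among oxidant genes, Cyba, a partner of NOX4, rose by 0.56 ± 0.11 and Gpx1 by 0.68 ± 0.08, and Prdx1 fell by 0.33 ± 0.04. Markers of proximal tubule segment 3 were lower in NOX4 cortex, 7 of 11 (8 adjusted over the list alone; median -0.55; adjusted p = 0.292 with an estimated correlation); Slc7a13 had -2.28 ± 0.39. The segment 3 score was 6.80 to 7.12 in SS LS cortex and 4.89 to 6.06 in NOX4 cortex over all diets. Within that NOX4 range lay SS HS7 replicates 3, 4 and 5 (5.44, 5.55 and 5.41) and SS HS21 replicates 3 and 5 (5.61 and 5.45). In all, 4812 genes were called (2540 higher, 2272 lower), and for the genes named 13 to 15 of 15 NOX4 libraries lay on the stated side of the SS mean, at adjusted p of 0.0126 or less. With the segment 3 score as covariate 872 were called, and Slc7a13 had 0.05, not called.

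In outer medulla the averaged comparison showed respiratory chain genes higher in NOX4 and matrix genes lower. Of 32 complex I genes 29 rose and none fell (31 adjusted over the list alone; median 0.41; Ndufb6 0.78 ± 0.07), and of 38 genes of complexes II to V 31 rose (33 adjusted over the list alone; median 0.36; Uqcrq 0.71 ± 0.08, Cox8a 0.72 ± 0.09). Fatty acid oxidation had 21 of 33 higher (23 adjusted over the list alone; Acadm 0.69 ± 0.11), and amino acid, arginine and creatine metabolism 21 of 35 higher and 1 lower (24 and 2 adjusted over the list alone; Odc1, of polyamine synthesis, 1.23 ± 0.23). Antioxidant and NRF2 target genes had 13 of 32 higher (15 adjusted over the list alone; Sod1 1.02 ± 0.23, Prdx6 0.63 ± 0.13). With an estimated correlation the calls on these lists ended, with adjusted p = 0.335, 0.335, 0.491, 0.491 and 0.491. SS HS7 replicate 3 had the highest score of proximal tubule segments 1 and 2 (8.37) and SS LS replicate 3 the lowest (2.70). Their fatty acid oxidation scores were 6.90 and 5.83, amino acid scores 7.66 and 5.19 and antioxidant scores 7.12 and 5.83. How far the rises of these lists follow the share of proximal tubule in the pieces stays open. Of 42 matrix genes 35 fell and 1 rose (36 and 1 adjusted over the list alone; median -0.82; adjusted p = 0.335 with an estimated correlation), with Tnc at -1.64 ± 0.20, Fbn1 at -1.12 ± 0.16 and Fn1 at -1.2 ± 0.18. Of 32 cell cycle genes 16 fell (16 adjusted over the list alone; adjusted p = 0.491 with an estimated correlation; Bub1 -0.77 ± 0.13).

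Receptor genes for angiotensin II fell in NOX4 outer medulla (Agtr1b -1.04 ± 0.14, Agtr1a -0.52 ± 0.12), as did Ednra (-0.60 ± 0.10), the macrophage gene Mrc1 (-1.16 ± 0.22) and the complement gene C7 (-1.09 ± 0.18). Segment 3 markers were higher here, 8 of 11 with 1 lower (9 and 1 adjusted over the list alone; median 1.19; adjusted p = 0.519 with an estimated correlation), the opposite of cortex; Slc7a13 had 1.21 ± 0.32 and Slc27a2 1.24 ± 0.32. In all, 4810 genes were called, 2430 higher and 2380 lower, with 13 to 15 of 15 NOX4 libraries on the stated side for the genes named, at adjusted p of 0.00561 or less. With the segment 3 score as covariate 1801 were called, and limma voom with quality weights called 8156.

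**Figure D3:**
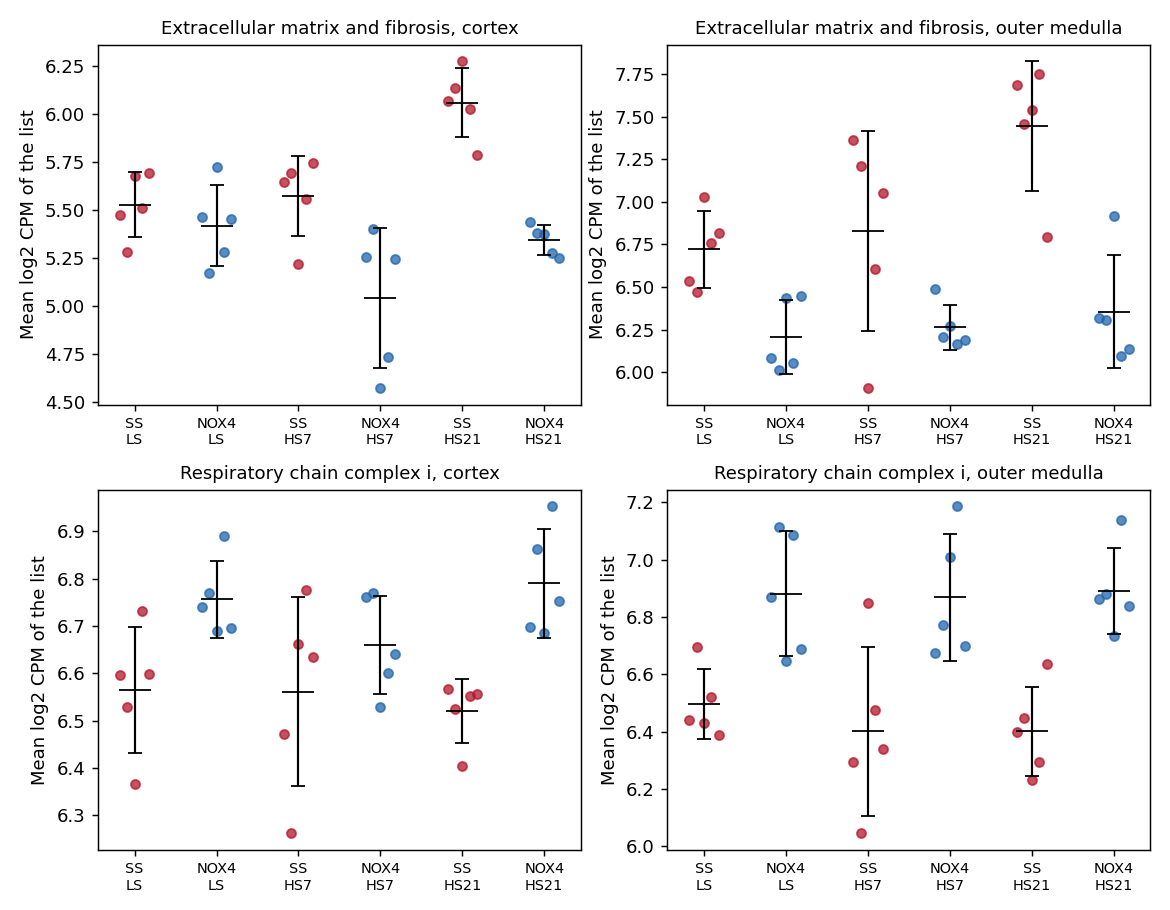
Mean log2 CPM of matrix genes (top) and complex I genes (bottom) in each library of cortex (left) and outer medulla (right); points are libraries, bars the mean and SD of 5 libraries, red SS and blue NOX4. Matrix genes lie lowest in NOX4 groups relative to SS at HS21, and the vertical scales differ between panels.

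At LS alone, 3342 genes differed between strains in cortex (1772 higher, 1570 lower in NOX4) and 2346 in outer medulla (1390 higher, 956 lower). At HS7 the counts were 2639 (1459 higher, 1180 lower) and 1519 (826 higher, 693 lower), the latter matched by 5 of 50 splits of the libraries, so that chance could not be excluded. All SS libraries precede all NOX4 libraries in library order, so strain and order coincide at each diet. SS at LS and HS7 stand first, before SS at HS21. Of the genes called for HS21 against HS7 in SS, 84.83% in cortex and 90.29% in outer medulla went the same way in NOX4 against SS at LS; of those called for HS21 against LS in SS, 76.95% and 70.58% did so in NOX4 against SS at HS7. Effects at LS and HS21 had a Pearson r of 0.314 in cortex (Spearman 0.344) and 0.501 in outer medulla (Spearman 0.524) across genes, which are not independent replicates. Of the genes called at LS, 80.0% in cortex and 87.6% in outer medulla had the same sign at HS21; these comparisons share no library. The segment 3 score was 5.47 ± 0.32 in NOX4 cortex and 6.99 ± 0.13 in SS cortex at LS (mean log2 CPM ± SD, n = 5), and 6.46 ± 0.73 against 4.85 ± 0.90 in outer medulla. With that score as covariate the counts at LS were 68 and 537, and without low-complexity libraries the cortex count was 1621. limma voom with quality weights called 4110 at LS in outer medulla. The HS7 counts fell to 184 and 0 in a fit of the compared groups alone, and the outer medulla LS count to 1462, 1356 and 1229 without NOX4 LS replicates 2, 3 and 4. The deposited adjusted p-values gave 3348 genes in cortex and 3538 in outer medulla at LS, 1431 and 232 at HS7, and 1937 and 5446 at HS21. By edgeR the HS21 counts were 152 and 258. Whether HS7 or HS21 had more genes thus depended on the fit, and the counts do not rank these diets. At HS7 the cortex count was 1447 by limma voom with quality weights, 1081 without NOX4 HS7 replicates 3 and 4 and 1582 without SS HS7 replicate 2. In outer medulla it was 73 without NOX4 HS7 replicates 3 and 4, 754 with the podocyte score as covariate, 1009 with no filter on low counts, 2519 by limma voom with quality weights and 2775 without low-complexity libraries. There it was 706, 499 and 3409 without SS HS7 replicates 1, 2 and 3 and 367 and 369 without NOX4 HS7 replicates 3 and 4.

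In SS cortex, injury, immune and matrix genes were higher at HS21 than at LS and mitochondrially encoded transcripts lower. Of 32 tubular injury genes 19 rose and 1 fell (22 and 2 adjusted over the list alone; median 0.53), with Lcn2 at 2.07 ± 0.31 (20.6 ± 6.61 CPM at HS21 and 4.86 ± 1.2 CPM at LS, n = 5 each), Spp1 at 1.95 ± 0.36 and Clu at 1.43 ± 0.18. Of 29 complement and coagulation genes 11 rose and 2 fell (18 and 2 adjusted over the list alone; C4b 3.05 ± 0.36, Cfi 2.27 ± 0.34), and of 42 matrix genes 17 rose (22 adjusted over the list alone; Tgfb1 1.13 ± 0.13, Loxl1 0.88 ± 0.12). Of 36 cytokine, chemokine and adhesion genes 9 rose (10 adjusted over the list alone; Icam1 0.61 ± 0.11), of 25 macrophage genes 9 (16; C1qa 1.00 ± 0.22), and of 18 antigen presentation genes 8 (10; RT1-Bb 0.78 ± 0.12). All 11 mitochondrially encoded genes tested fell (11 adjusted over the list alone; median -0.54), with Mt-nd3 at -0.96 ± 0.12 and Mt-nd5 at -0.66 ± 0.09. With an estimated correlation the calls on these 7 lists ended, with adjusted p = 0.285, 0.285, 0.361, 0.197, 0.361, 0.197 and 0.197.

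Single genes of salt handling and redox control moved in SS cortex too. Ptgs2, the prostaglandin synthase gene of the macula densa, fell by 2.51 ± 0.53 and the thick ascending limb cotransporter gene Slc12a1 by 0.83 ± 0.19. Gstp1 fell by 1.16 ± 0.17 and Gclm, of glutathione synthesis, by 1.29 ± 0.35, and the glucose cotransporter gene Slc5a2 rose by 0.71 ± 0.17. In all, 2499 genes were called (1278 higher, 1221 lower), in 5 of 5 HS21 libraries for the genes named and at adjusted p of 0.0123 or less. SS LS held 3 low-complexity libraries and a mitochondrial read share of 14.4 ± 1.01%, against 11.9 ± 0.802% at HS21, and stands before SS HS21 in library order; without low-complexity libraries 930 genes were called, and 1541 without SS HS21 replicate 3. The segment 3 score was 6.99 ± 0.13 at LS and 6.11 ± 0.59 at HS21, and its marker Slc7a13 had 2131 ± 642 and 640 ± 456 CPM (SD, n = 5). With that score as covariate 891 genes were called. The deposited adjusted p-values gave 3107.

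In SS outer medulla, injury, matrix and complement genes were higher at HS21 than at LS. Havcr1, which encodes the injury marker KIM-1, rose by 3.34 ± 0.50 (65.9 ± 25.8 CPM at HS21 and 6.41 ± 2.39 CPM at LS, n = 5 each), Clu by 1.92 ± 0.31 and the fibrinogen gene Fgb by 3.24 ± 0.72, while Egf fell by 1.17 ± 0.23. In all 11 of 32 injury genes rose and 1 fell (15 and 2 adjusted over the list alone). Of 42 matrix genes 13 rose (20 adjusted over the list alone; Eln 2.16 ± 0.32, Postn 2.64 ± 0.45, and Acta2, also on the smooth muscle list, 1.77 ± 0.27), and of 30 complement and coagulation genes 10 (15 up and 1 down adjusted over the list alone; C4b 1.72 ± 0.30, and Cfd, also on the adipose tissue list, 3.07 ± 0.55). Of 37 sodium and potassium transport genes 6 fell (10 adjusted over the list alone), with the sodium-proton exchanger gene Slc9a3 at -1.12 ± 0.27 and Kcnj16 at -0.69 ± 0.14, and of 11 mitochondrially encoded genes 7 fell (11 adjusted over the list alone; Mt-co2 -0.70 ± 0.15). With an estimated correlation the calls on these 5 lists ended, with adjusted p = 0.669, 0.669, 0.329, 0.345 and 0.345. In all, 1557 genes were called (836 higher, 721 lower), in 5 of 5 HS21 libraries for the genes named and at adjusted p of 0.00967 or less. SS LS held 3 low-complexity libraries and a mitochondrial read share of 12.5 ± 1.19%, against none and 9.12 ± 0.753% at HS21, and stands before SS HS21 in library order. The smooth muscle and pericyte score was 3.88 ± 0.23 at LS and 4.87 ± 0.33 at HS21 (mean log2 CPM ± SD, n = 5), and the adipose tissue score 0.56 ± 0.50 and 2.00 ± 0.15, with no overlap between libraries of the 2 groups for either. The count was 767 without SS HS21 replicate 4 and 897 without SS HS21 replicate 1, and limma voom with quality weights called 3666. The deposited adjusted p-values gave 2751.

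At 7 days some of these genes were called in SS, but chance could not be excluded for either count: 4 of 50 splits of the libraries in cortex and 6 of 50 in outer medulla gave as many genes. In cortex C4b had risen by 2.09 ± 0.35, Lcn2 by 1.46 ± 0.31 and Cfi by 1.61 ± 0.34, and Ptgs2 had fallen by 2.71 ± 0.55 and Gstp1 by 1.05 ± 0.17, at adjusted p of 0.0144 or less. In outer medulla Havcr1 had risen by 2.23 ± 0.48 (30.3 ± 6.60 against 6.41 ± 2.39 CPM, adjusted p = 0.0246) and the clock-linked gene Hlf by 2.69 ± 0.52 (adjusted p = 0.0161). At HS21 against HS7, RT1-CE16 and Vasp were higher in SS cortex (1.01 ± 0.11 and 0.94 ± 0.12) and Zbtb20 lower by 2.04 ± 0.26. Rps2 and Nenf were higher in SS outer medulla (0.98 ± 0.14 and 0.86 ± 0.14). SS HS7 stands before SS HS21 in library order, so time on salt and order coincide here. Zbtb20 had 60.2 CPM in SS HS7 cortex and 14.7 in SS HS21, but 13, 17.7 and 16.9 in NOX4 at LS, HS7 and HS21. Of the genes called here in cortex, 84.83% went the same way in NOX4 against SS at LS and 63.96% in NOX4 at HS21 against HS7. That difference of 20.87 percentage points had a jackknife SD of 11.45. Counts for HS7 against LS were 341 (178 higher, 163 lower) in cortex and 374 (245 higher, 129 lower) in outer medulla. For HS21 against HS7 they were 1404 (685 higher, 719 lower) and 103 (66 higher, 37 lower), the latter matched by 5 of 50 splits. Without low-complexity libraries the HS7 counts were 13 and 0 and the outer medulla HS21 against HS7 count was 1, and a fit of the compared groups alone called 1 gene for HS7 in each tissue. With the segment 3 score as covariate the HS7 counts were 161 and 31, by limma voom with quality weights 6 and 2, and by DESeq2 910 and 1434. The deposited adjusted p-values gave 107 and 62 for HS7 against LS and 1474 and 342 for HS21 against HS7. The replicate block gave 216 for HS7 and 55 for HS21 against HS7 in outer medulla, where limma voom gave 342 and DESeq2 346 for the latter. The cortex HS7 count was 190 and 819 without SS LS replicates 4 and 5 and 762 and 773 without SS HS7 replicates 1 and 2. The cortex HS21 against HS7 count was 782 without SS HS7 replicate 2 and 695 and 796 without SS HS21 replicates 3 and 4. In outer medulla 9 libraries moved the HS7 count over 1.5-fold, from 70 without SS HS7 replicate 3 to 1456 without SS HS7 replicate 2. There 7 moved the HS21 against HS7 count, from 16 without SS HS7 replicate 4 to 314 without SS HS7 replicate 5.

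In NOX4 rats no gene passed the threshold for salt, though the same injury genes had higher values. In cortex edgeR called 0 genes for HS7 against LS, HS21 against LS and HS21 against HS7, with 782, 236 and 559 genes at an unadjusted p under 0.05. DESeq2 called 18, 7 and 2, limma voom 1, 115 and 0, and the deposited values 12, 36 and 8. In outer medulla edgeR called 0, 0 and 0, with 2162, 249 and 1338 genes at an unadjusted p under 0.05; DESeq2 called 124, 5 and 73, limma voom 2, 5 and 0, and the deposited values 56, 43 and 11. Without NOX4 HS7 replicate 1, 2 or 5, HS7 against LS had 11, 5 and 13 genes in cortex and 2, 57 and 66 in outer medulla. HS21 against HS7 had 23, 107 and 82 in outer medulla. HS21 against LS had 1 there without NOX4 LS replicate 3 or NOX4 HS21 replicate 5. At HS21 Spp1 had 909 ± 579 CPM in NOX4 cortex against 303 ± 144 CPM at LS (log2 fold change 1.59 ± 0.35, adjusted p = 0.269), and Havcr1 26 ± 17 against 7.83 ± 5.52 CPM (1.73 ± 0.45, adjusted p = 0.797). In outer medulla Havcr1 had 42.2 ± 34.4 against 7.55 ± 6.73 CPM (2.48 ± 0.48, adjusted p = 0.272) and Clu 406 ± 239 against 196 ± 46.5 CPM (1.05 ± 0.31, adjusted p = 1.00); each was higher than the LS mean in 5 of 5 libraries. The Havcr1 value in outer medulla was 1.86 without NOX4 HS21 replicate 3 (101.3 CPM) and 3.16 without NOX4 LS replicate 3. As a list, tubular injury genes rose in NOX4 cortex at HS21 (0 of 32 called over all genes, 4 adjusted over the list alone; median 0.27; adjusted p = 0.0386 with an estimated correlation). Smooth muscle and pericyte genes fell there (0 of 16 over all genes, 4 adjusted over the list alone; median -0.31; adjusted p = 0.0386 with an estimated correlation).

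Across genes, which are not independent replicates, the salt effects of the strains at day 21 had a Pearson r of 0.124 in cortex (Spearman 0.151) and 0.322 in outer medulla (Spearman 0.347), with a jackknife SD over libraries of 0.105 and 0.117. Of the genes called in SS, 62.4% in cortex and 75.3% in outer medulla went the same way in NOX4. At day 7 r was 0.00764 (Spearman -0.0308) and 0.263 (Spearman 0.294), with jackknife SDs of 0.0719 and 0.167, and 50.1% and 80.7% went the same way. These comparisons share no library.

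The test of whether the salt effect differed between strains called 164 genes in cortex at HS21 (78 with a higher and 86 with a lower log2 effect in NOX4). Tgfb1 (-1.15 ± 0.18) and Loxl1 (-0.86 ± 0.17), which rose in SS, were among them, as were the antigen presentation gene Tapbp (-0.74 ± 0.15) and the interferon-induced gene Bst2 (-1.02 ± 0.20). Mt-nd3, which fell in SS, had 0.77 ± 0.17. As a list, matrix genes had a smaller effect in NOX4 (0 of 42 higher, 4 lower; 16 lower adjusted over the list alone; median -0.56; adjusted p = 0.429 with an estimated correlation, which ended the call), and mitochondrially encoded genes a higher one (2 of 11, 5 adjusted over the list alone; median 0.40; adjusted p = 0.429 with an estimated correlation, also ending it). The smallest p-values were of Zbtb20 (2.80 ± 0.36, adjusted p = 0.000227), Hipk2 (1.59 ± 0.22) and Vbp1 (-0.75 ± 0.12). In SS cortex Zbtb20 had 78.6 CPM at LS, 60.2 at HS7 and 14.7 at HS21, and in NOX4 13, 17.7 and 16.9. Of the 4 groups in this test only SS LS stands before the others at the start of the library order. The count was 42 with the segment 3 score as covariate, 79 without low-complexity libraries, 103 with the replicate block, 109 with no filter on low counts, 522 by DESeq2 and 993 by limma voom with quality weights. Any of 14 of the 20 libraries moved it over 1.5-fold, down to 51 without SS HS21 replicate 3.

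At HS7 the interaction called 2 genes in cortex, Map2k6 (-1.67 ± 0.27, adjusted p = 0.0112) and Rab32 (-0.57 ± 0.10), the latter lost when any 1 of 9 libraries was left out; DESeq2 called 100, and 0 were called by edgeR with the segment 3 score as covariate. In outer medulla edgeR called 0 genes at HS7 (1676 at an unadjusted p under 0.05; DESeq2 19, limma voom 0). At HS21 it called 4, of which Hnrnpa0 (-0.95 ± 0.16) was lost without any 1 of 9 libraries; the other 3, named after their values were seen, were LOC100361061, AABR07015081.1 and AABR07015081.2, with -1.23 ± 0.22, 3.18 ± 0.59 and 2.30 ± 0.43. That count was 11 with the podocyte score and 13 with the segment 3 score as covariate, 22 without low-complexity libraries, 125 by DESeq2 and 1432 by limma voom with quality weights.

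The tissue labels were checked by segment markers in SS at LS, where 8770 of 16326 genes differed (4311 higher and 4459 lower in outer medulla). The early proximal tubule gene Slc6a19 (-8.04 ± 0.95), the distal convoluted tubule gene Slc12a3 (-6.24 ± 0.70) and Slc26a4 (-7.38 ± 0.74) were lower in outer medulla. The thick ascending limb genes Slc12a1 (2.80 ± 0.22) and Cldn19 (2.80 ± 0.22) and the collecting duct gene Aqp2 (2.49 ± 0.29) were higher, at adjusted p of 1.63e-08 or less for all genes named here. The averaged strain effect differed between tissues for 1796 genes (1228 with a higher log2 effect in outer medulla, 568 lower), with the smallest p-values for Ppp2r2c (-2.16 ± 0.26), Robo2 (-1.36 ± 0.17), Mcoln2 (3.41 ± 0.43) and the chloride channel gene Cftr (3.94 ± 0.52). The SS response at HS21 differed between tissues for 32 genes (19 higher, 13 lower), among them Gstp1 (1.3 ± 0.25), Pde8a (-0.90 ± 0.16) and Ryr1 (1.65 ± 0.32). The first count was 3324 without SS HS7 outer medulla replicate 3, and 9 libraries moved the second over 1.5-fold, from 10 without SS HS21 outer medulla replicate 4 to 103 without SS LS outer medulla replicate 1.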

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

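The tests of library order, low-complexity libraries, the slope between strains, the segment 3 covariate and the pieces of tissue were chosen only after the results they measure were seen; those on gene length and on other splits of the libraries were not. The condition on cortex markers was added to the test of more cortex in the outer medulla pieces after its result was seen, and changed its outcome from argued against to open.

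The effect of 21 days of salt differed between strains for 164 genes in cortex and 4 in outer medulla, by the interaction test, in which SS LS alone of the 4 groups lies at the start of the library order, so an order effect would enter it in full. Those named in cortex were Tgfb1, a profibrotic growth factor gene (-1.15), the matrix gene Loxl1 (-0.86), the antigen presentation gene Tapbp (-0.74), Bst2 (-1.02), Vbp1 (-0.75), Mt-nd3 (0.77), Hipk2 (1.59) and Zbtb20 (2.80). In outer medulla it was Hnrnpa0 (-0.95). At 7 days the effect differed for 2 genes in cortex, the kinase gene Map2k6 (-1.67) and Rab32 (-0.57). Between tissues, the averaged strain effect differed for 1796 genes, with Cftr (3.94), Mcoln2 (3.41), Ppp2r2c (-2.16) and Robo2 (-1.36) named, and the SS effect of 21 days of salt for 32, with Gstp1 (1.3), Ryr1 (1.65) and Pde8a (-0.90).

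Single libraries lay far from the other 4 of their group in 6 of 72 sets of 5 values looked at (Nox4, 3 library measures, and Slc7a13, Zbtb20 and Havcr1); chance gives this in about 1 in 20 sets, or 3.6 of 72. Nox4 had 10.3 CPM in NOX4 LS outer medulla replicate 4 and 15.1 CPM in NOX4 HS7 outer medulla replicate 2, and Havcr1 101.3 CPM in NOX4 HS21 outer medulla replicate 3. The total was 19.25 M counts in SS HS7 cortex replicate 3. NOX4 LS cortex replicate 3 held 17370 genes at 10 M counts, and 9.596% of the counts of NOX4 HS21 outer medulla replicate 3 were mitochondrial.

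More genes were called for 21 days of salt in SS than in NOX4 (2499 and 0 by edgeR in cortex, with 236 in NOX4 at an unadjusted p under 0.05, DESeq2 7 and limma voom 115). Without the low-complexity libraries SS had 930 genes in cortex and 1421 in outer medulla, which argues against these libraries as the whole cause. Library order stays open: SS at LS and HS7 lie on its other side, and of the genes called in SS at HS21 against LS the share going the same way in NOX4 against SS at HS7, which crosses the same boundary, was higher by 14.53 percentage points in cortex than in the NOX4 salt response (jackknife SD 13.09) and differed by -4.689 in outer medulla (SD 10.96); for those called at HS21 against HS7, set against NOX4 against SS at LS, it was higher by 20.87 in cortex (SD 11.45) and 32.04 in outer medulla (SD 20.56), all within 2 SD. Over the genes called in SS cortex the slope of the NOX4 change on the SS change was 0.0948, which a smaller salt response without NOX4 and an order effect in SS would both give. Choosing genes by their call in SS favours large SS values and can also lower this slope. The smaller response and the order effect cannot be told apart, because order and group coincide in SS. Order and strain likewise coincide for NOX4 against SS at each diet and averaged over diets.

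After 21 days of salt, matrix genes were lower and respiratory chain genes (70, of complexes I to V together) higher in NOX4 in both tissues by the preset correlation. In cortex matrix genes and complex I held with an estimated correlation (adjusted p = 0.0138 and 0.0204) and complexes II to V did not (0.051), and in outer medulla none of the 3 lists held (0.0919, 0.144 and 0.144). A trend with gene length is argued against as the whole cause: the medians lay at percentiles 0 (matrix) and 100 (respiratory chain) of 10000 lists matched on length and level in each tissue, but such lists had medians of 0.11 in cortex and 0.09 in outer medulla where the respiratory chain had 0.21 and 0.43, so part of its rise goes with length and level. With the segment 3 score as covariate the matrix medians were -0.67 in cortex and -0.81 in outer medulla (from -0.66 and -1.13), and the respiratory chain medians 0.14 and 0.35 (from 0.21 and 0.43), which argues against the share of segment 3 as the whole cause. A share of other cell types was not tested for matrix genes, more cortex in the NOX4 outer medulla pieces stays open, and a difference between the strains in kidney injury stays open as untested. Library order coincides with strain at HS21 and was not tested for these lists.

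Averaged over diets, segment 3 genes were lower in NOX4 cortex and higher in NOX4 outer medulla. Some SS HS7 and SS HS21 cortex libraries had segment 3 scores within the NOX4 range. More cortex in the NOX4 outer medulla pieces cannot be told apart from a strain difference either: podocyte genes had a median of -0.13 there with 6 of 13 called lower and none higher, but only 2 of the 13 had an SS LS level in outer medulla under 10% of that in cortex. Those 2 were higher in NOX4 (median 1.36), as were 2 distal convoluted tubule markers under that limit (1.03), none of them called, and 12 of 13 such markers of proximal tubule segments 1 and 2, 4 of them called (median 1.3). An outer stripe moved from the cortex piece to the outer medulla piece cannot be told apart from a strain difference in segment 3: thick ascending limb genes had a median of 0.0202 in outer medulla, with members going both ways. Where the pieces were divided is not given in the labels.

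Other splits of the libraries of the compared groups were counted for each comparison, 50 where more existed, 30 between tissues and 20 where the real count was 0. In cortex no other split gave as many genes for NOX4 against SS at LS (3342 genes, highest other split 409), HS7 (2639, 1396), HS21 (152, 0) or averaged (4812, 14). Nor did any for SS at HS21 against LS (2499, 6) or against HS7 (1404, 305). Each was matched by 1 of 50 splits, the real one, which argues against chance. It does not exclude chance, as this is the smallest share possible and shares were not adjusted over comparisons. A split of labels also does not separate strain or diet from a library order that coincides with it. In outer medulla the same held, again 1 of 50, at LS (2346; 1), at HS21 (258; 1), averaged (4810; 1) and for SS at HS21 against LS (1557; 52). Between tissues 1 of 30 splits, the real one, gave as many genes for outer medulla against cortex (8770, highest other 4612). The same held for the difference of the averaged strain effect (1796, 167) and of the SS effect at HS21 (32, 5). Splits for these differences exchanged strains or diets within a tissue, which also removed the effect that the tissues share. They cannot exclude chance for the differences alone.

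Chance could not be excluded for SS at HS7 against LS in cortex (341 genes; 4 of 50 splits gave as many, the highest 627) or outer medulla (374; 6 of 50, highest 1587), for NOX4 against SS at HS7 in outer medulla (1519; 5 of 50, highest 3608) or for SS at HS21 against HS7 in outer medulla (103; 5 of 50, highest 1530). In outer medulla some splits called several times the real count, which points to a structure of the samples other than the groups. Proximal tubule segments 1 and 2 scored 8.37 in SS HS7 replicate 3 and 8.13 in NOX4 HS7 replicate 2, against 2.70 to 6.67 in the other 28 outer medulla libraries, and SS HS7 replicate 3 also had the lowest thin limb (3.99) and principal cell (4.34) scores. The lowest thick ascending limb scores were those of NOX4 HS7 replicates 3 (7.28) and 4 (7.42) and SS HS7 replicate 3 (7.42). The cortex interaction at HS7 (2 genes, highest other 1) was matched by 1 of 50 splits, the real one. Those at HS21 were matched by 2 of 50, the real one included (164 in cortex, 4 in outer medulla with a highest other of 4). These splits exchanged strains within each diet and so also removed the strain effect that the diets share. They cannot exclude chance for the interaction alone. In cortex at HS21 the other split called 2355 genes, which again points to such a structure. For NOX4 diets, 20 of 20 splits gave at least the real count of 0 by edgeR (highest others 1, 0 and 0 in cortex and 0, 1 and 1 in outer medulla), as did 20 of 20 for the outer medulla interaction at HS7 (0; highest other 0); with a real count of 0 no share under 0.05 was possible.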

How the results depend on the processing

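Leaving out low-complexity libraries, limma voom with quality weights, the segment 3 covariate and leaving out NOX4 HS7 outer medulla replicates 3 and 4 were chosen after seeing the data; the other alternatives were not. Adjusted p-values and counts are from edgeR unless another tool is named. The fit of the compared groups alone was not run for the tissue difference of SS at HS21 against LS. Replicate numbers showed no clear pairing of libraries. Within a tissue the residuals of the same number had a mean r of 0.0155 (cortex, 16 of 75 pairs over 0.1) and -0.00511 (outer medulla, 22 of 75). Between tissues it was 0.0228 (6 of 30 over 0.1), with 7 of 30 cortex libraries closest to their own number. In most cases the cortex and outer medulla libraries of the same group and number have neighbouring library names. The labels do not say whether they came from the same rat, and a low r does not exclude it. The comparisons between tissues took them as independent. Depth and library complexity limit genes near 2 to 5 CPM in the 11 low-complexity libraries. Except where a setting's own construction shows it, the cause of a change was not tested. Counts below are of genes past the threshold.

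With no filter on low counts more genes were tested, and the cortex interactions had 1 (HS7) and 109 (HS21) genes. Outer medulla NOX4 against SS had 1009 at HS7 and 171 at HS21, and the tissue difference of SS at HS21 against LS had 20. The r between the salt effects of the strains was then 0.0636 at HS7 and 0.0995 at HS21 in outer medulla. In cortex it was -0.0133 at HS7 and 0.0274 at HS21, against 0.0076 and 0.124 with the filter. With the replicate number as a block, the cortex HS21 interaction had 103, outer medulla NOX4 against SS at HS21 146, SS at HS7 against LS 216, SS at HS21 against HS7 55, the HS7 interaction 1 (edgeR 0 without the block, 1676 at an unadjusted p under 0.05), and the tissue difference of SS at HS21 13.

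Without low-complexity libraries, which leaves fewer samples, cortex counts were 1621 (NOX4 against SS at LS), 583 (HS21), 13 (SS HS7 against LS), 930 (SS HS21 against LS), 2 and 2 (NOX4 HS7 and HS21 against LS), and 1 and 79 (interactions at HS7 and HS21). In outer medulla they were 2775 (NOX4 against SS at HS7), 2297 (HS21), 0 by edgeR (SS HS7 against LS), 1 (SS HS21 against HS7), 13 (NOX4 HS7 against LS) and 22 (HS21 interaction); the tissue differences had 3511 (averaged strain effect) and 12 (SS at HS21). Without NOX4 HS7 cortex replicates 3 and 4, NOX4 against SS at HS7 had 1081, the HS7 interaction 0 by edgeR, and r at HS7 was 0.0865. Without the outer medulla ones, NOX4 against SS at HS7 had 73, NOX4 HS7 against LS 1 and NOX4 HS21 against HS7 1.

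With the segment 3 score as covariate, cortex had 68 (NOX4 against SS at LS), 60 (HS21), 872 (averaged), 161 (SS HS7 against LS), 891 (SS HS21 against LS), and 0 by edgeR and 42 (interactions at HS7 and HS21). Outer medulla had 537 (LS), 12 (HS21), 1801 (averaged), 31 (SS HS7 against LS) and 13 (HS21 interaction). Slc7a13 in cortex, averaged, reversed to 0.0541 (adjusted p = 0.846), and 4 outer medulla lists reversed: at HS21 interferon response (adjusted p = 0.0037) and proximal tubule segments 1 and 2 (0.33), and averaged macrophages (0.133) and segments 1 and 2 (0.0628). With the podocyte score as covariate outer medulla had 754 (NOX4 against SS at HS7) and 11 (HS21 interaction).

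limma voom with quality weights gave in cortex 1447 (NOX4 against SS at HS7), 2161 (HS21), 6 (SS HS7 against LS), 1 and 115 (NOX4 HS7 and HS21 against LS) and 1 and 993 (interactions), with r between the strains' salt effects of 0.117 at HS7 and 0.266 at HS21. In outer medulla it gave 4110 (LS), 2519 (HS7), 7461 (HS21), 8156 (averaged), 2, 3666 and 342 (SS HS7 against LS, HS21 against LS, HS21 against HS7), 2 and 5 (NOX4 HS7 and HS21 against LS) and 1432 (HS21 interaction). The fit of the compared groups alone gave in cortex 184 (HS7), 1237 (HS21), 1 (SS HS7 against LS) and 4 (NOX4 HS21 against LS), and in outer medulla 0 by edgeR (HS7), 3703 (HS21) and 1 (SS HS7 against LS). DESeq2 gave in cortex 339 (HS21), 910 (SS HS7 against LS), 18, 7 and 2 (NOX4 HS7 against LS, HS21 against LS, HS21 against HS7) and 100 and 522 (interactions). In outer medulla it gave 640 (HS21), 1434 (SS HS7 against LS), 346 (SS HS21 against HS7), 124, 5 and 73 (NOX4 diets in the same order) and 19 and 125 (interactions), and 127 for the tissue difference of SS at HS21.

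Leaving out 1 library gave these ranges in cortex, with the library left out: NOX4 against SS at HS7 1582 (SS HS7 replicate 2) to 3475 (SS HS7 replicate 3) and at HS21 29 (SS HS21 replicate 3) to 290 (SS HS21 replicate 5), moved over 1.5-fold by 8 libraries. SS HS7 against LS ran 190 (SS LS replicate 4) to 819 (SS LS replicate 5), with 762 and 773 without SS HS7 replicates 1 and 2; SS HS21 against LS 1541 (SS HS21 replicate 3) to 2703 (SS LS replicate 1); and SS HS21 against HS7 695 (SS HS21 replicate 3) to 1922 (SS HS7 replicate 3), with 782 without SS HS7 replicate 2 and 796 without SS HS21 replicate 4. NOX4 HS7 against LS ran from 0 to 13 (NOX4 HS7 replicate 5), with 11 and 5 without replicates 1 and 2. The HS7 interaction ran 1 (SS LS replicate 4 among others) to 27 (NOX4 HS7 replicate 1) and the HS21 interaction 51 (SS HS21 replicate 3) to 240 (SS LS replicate 5), each moved by 14 libraries.

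In outer medulla NOX4 against SS at LS ran 1229 (NOX4 LS replicate 4) to 2338 (SS LS replicate 1), with 1462 and 1356 without NOX4 LS replicates 2 and 3. At HS7 it ran 367 (NOX4 HS7 replicate 3) to 3409 (SS HS7 replicate 3), with 706, 499 and 369 without SS HS7 replicates 1 and 2 and NOX4 HS7 replicate 4, and at HS21 28 (NOX4 HS21 replicate 4) to 834 (SS HS21 replicate 5), moved by 9 libraries. SS HS7 against LS ran 70 (SS HS7 replicate 3) to 1456 (SS HS7 replicate 2), moved by 9; SS HS21 against LS 767 (SS HS21 replicate 4) to 1505 (SS LS replicate 1), with 897 without SS HS21 replicate 1; SS HS21 against HS7 16 (SS HS7 replicate 4) to 314 (SS HS7 replicate 5), moved by 7. NOX4 HS7 against LS ran 0 to 66 (NOX4 HS7 replicate 5), with 2 and 57 without replicates 1 and 2; HS21 against LS 0 to 1 (NOX4 LS replicate 3 or NOX4 HS21 replicate 5); HS21 against HS7 0 to 107 (NOX4 HS7 replicate 2), with 23 and 82 without replicates 1 and 5. The HS7 interaction ran 0 to 1 (SS LS replicate 1) and the HS21 interaction 0 to 7 (SS LS replicate 1), moved by 16. Nox4 in percent of SS ran 38.5 (NOX4 LS replicate 4) to 57.2 (NOX4 LS replicate 2) at LS and 9.95 (NOX4 HS7 replicate 2) to 34.6 (SS HS7 replicate 3) at HS7. Between tissues the averaged strain effect ran 1498 (NOX4 LS outer medulla replicate 3) to 3324 (SS HS7 outer medulla replicate 3) and the SS effect at HS21 10 (SS HS21 outer medulla replicate 4) to 103 (SS LS outer medulla replicate 1), moved by 9.

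Averaged over diets, NOX4 against SS stayed within 1.5-fold when any 1 library was left out, at 4329 to 5272 genes in cortex and 4109 to 6484 in outer medulla, as did outer medulla against cortex at 8349 to 8740. Of 147 list calls in the reported comparisons, 12 held with an estimated correlation and 135 did not; 145 held with DESeq2's size factors, 147 with the replicate block and 138 without low-complexity libraries. With the segment 3 covariate 106 of 141 held, 31 were lost and 4 reversed.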

Other observations

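Every test in this part was chosen only after the result it measures was seen.

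Some genes passed the threshold for NOX4 against SS at each of LS, HS7 and HS21 with the same sign: 45 in cortex (23 higher and 22 lower in NOX4) and 53 in outer medulla (14 higher and 39 lower).

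Reads of Nox4 remained in NOX4 cortex. If reads of SS libraries had been mixed into NOX4 libraries, the level in NOX4 would follow that in SS between diets. The ratio of HS7 to LS was 0.982 ± 0.0627 (SE) in NOX4 and 1.34 ± 0.201 in SS. The difference of 0.36 had an SE of 0.21, so this ratio could not tell mixing apart from transcription of the altered gene. Reads of SS LS libraries mixed in would leave other genes near the Nox4 share too. At LS in cortex Nox4 had a log2 fold change of -2.25. Leaving out each library, Muc13 had -6.18 to -5.20 there and Cfhr2 -8.78 to -5.52. These values argue against SS LS reads as the whole source at LS, though both genes are among the lowest of that comparison.

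A second question was whether genes near Nox4 differ between strains because of DNA around the locus. Of 23 tested genes within 5 Mb, 10 were called for the averaged strain effect in cortex (43.48%, against 31.7% of other genes; Fisher's exact p = 0.262) and 5 in outer medulla (21.74%, against 30.5% of other genes; exact p = 0.497). The genes are few, and this leaves DNA around Nox4 neither shown nor excluded.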
